A study of Mus musculus with 12 samples.

How the data were processed

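Polyadenylated RNA from 12 mouse libraries was sequenced in 4 groups of 3, and 1 table of values per gene was analysed. The labels put 6 libraries under tumour, with cancer cells as the cell type: 3 from KPC cells (mouse pancreatic cancer cells with mutant Kras and Trp53 alleles) that were wild type for Grin2d, and 3 from KPC cells with a Grin2d knockout. The other 6 were labelled as dorsal root ganglia (DRG) of thoracic levels 8 to 12, from mice that carried a wild-type or a knockout tumour. The ganglia themselves were labelled wild type, so KO and WT name the tumour that the mouse carried. Samples from patients, which the study's design text also mentions, were not analysed here.

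The deposited table is named for FPKM, but each value in its 12 library columns is a whole number, the columns total between 27.521 M and 41.049 M, and the values were therefore taken as counts. The deposited counts carry no normalization. Each library has a column of its own, which does not show whether several animals were pooled in a library. A column of gene length in bases accompanies the counts per the file headers. The submitters' processing notes name fastp, HISAT2 2.0.5, Bowtie2 2.3.4.3, featureCounts and Subread, without saying which step each one did or whether reads were assigned by strand. The same notes name only human genome builds (GRCh38 and hg38), while the table lists mouse gene identifiers. Of its 56748 identifiers, 52073 were found in the GENCODE M21 annotation of GRCm38, and 1472 of those had the same start and end there. Positions are given as the table lists them, and the build behind them is not named.

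Levels in CPM, counts scaled by the library total, were computed from the deposited counts, and FPKM from the CPM and the gene lengths. Genes were tested when their mean FPKM over the libraries of a comparison was at least 0.5. The design fixed before the data were examined had assumed FPKM and limma on log2(FPKM + 0.5). Since the values were counts, the test became the quasi-likelihood test of edgeR 4.0.16 with TMM normalization in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The limma fit (limma 3.58.1) was kept as an alternative. Standard errors (SE) of log2 fold changes came from log2 CPM values with a prior count of 2. Grin2d was also compared with an exact two-sided permutation test.

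There were 3 planned comparisons: tumour KO with tumour WT, DRG KO with DRG WT, and the difference between those 2 effects over all 12 libraries. Another comparison, DRG KO with tumour WT, was added after the libraries had been compared with one another. Pearson r between libraries was computed across genes on log2(CPM + 1), and genes are not independent replicates. For pairs of libraries, a chi-square per gene was computed over genes with at least 20 counts in the pair, to see whether columns were copies of one another. Whether replicate numbers paired the libraries was checked by correlating deviations from the group means.

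The 43 gene lists were fixed in advance, and all 671 members were matched by symbol. They were glutamate receptors, glutamate release and handling, postsynaptic scaffold and adhesion, presynaptic vesicle release, immediate early genes, axon guidance and neurotrophic factors, and proliferation. Cancer cell lists were epithelial and ductal, classical pancreatic cancer, basal-like pancreatic cancer, and mesenchymal transition. Lists of other cell types were pancreatic acinar, pancreatic endocrine, matrix fibroblast, inflammatory fibroblast, macrophage, neutrophil, T and NK cell, B and plasma cell, dendritic cell and MHC class II, endothelial, peptidergic nociceptor, non-peptidergic and itch neuron, myelinated sensory neuron, satellite glia, Schwann cell and myelin, central nervous system glia, skeletal muscle, adipocyte, erythroid, and cartilage and bone. Process lists were MHC class I presentation, interferon response, NF-kB and inflammatory cytokines, hypoxia and glycolysis, nuclear oxidative phosphorylation, cholesterol synthesis, p53 targets, endoplasmic reticulum stress, and nerve injury and regeneration. Lists for RNA quality and handling were mitochondrially encoded, cytosolic ribosomal protein, and heat shock. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists, with camera at an estimated correlation and fry beside it. Members past the threshold were also counted adjusted over the list alone.

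Named genes followed a rule fixed in advance. In each of the tumour and DRG comparisons they were the 10 higher and 10 lower genes with the greatest fold change among those past the threshold, with a mean FPKM of at least 1 and no overlap between groups, leaving out predicted genes, pseudogenes and receptor segments. From each list described, up to 4 members with the smallest p were named, and 5 genes for the difference. A fold against a group at 0 counts was computed against a floor of 3 counts over the group, and for 1 to 3 counts the pooled ratio is given with its exact 95% counting interval.

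The steps were tested on simulated data with 200 changed genes drawn from the real means and library sizes. For genes changed by 1 and by 2 on the log2 scale, 59% and 95% were recovered in tumour (12886 genes), 88% and 96% in DRG (13981 genes), 37% and 87% for the difference (13744 genes), and 82% and 99% for DRG KO with tumour WT (12604 genes). Of the calls, 6.67%, 8.46%, 5.34% and 3.72% were genes that had not been changed. The changed list was called in each simulation and 0 of 40 unchanged lists were. Genes were drawn independently there, so the list tests were not tried on correlated genes. The 200 changed genes are also far fewer than the planned comparisons called, so normalization with many changed genes was not tried.

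Alternatives chosen in advance were pseudocounts of 0.1 and 1, no filter or a mean FPKM of at least 2, rescaling each sample to the same total, median centring, quantile normalization, limma without a trend or with array weights, leaving out each library, all 12 libraries in one fit, a replicate block for DRG, and the other list tests. Those on the log2 scale changed the limma fit. Limma as designed, the main test fixed in advance, became an alternative when edgeR replaced it. Added after the data had been seen were RLE factors, library totals alone, DESeq2 1.42.0, filterByExpr, a correction for gene length by lowess in each library, WT replicate 3 as the only WT library, and the direction of each library's gene length trend as a block.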

Results

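Polyadenylated RNA was sequenced in 12 mouse libraries that fall into 4 groups of 3. The tumour groups were labelled as cancer cells of KPC tumours, grown in the pancreas of wild-type mice from cells either wild type (tumour WT, replicates 1, 2 and 3) or knocked out for Grin2d (tumour KO, replicates 18, 21 and 23). The DRG groups were labelled as dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, of mice that carried a wild-type (DRG WT) or a knockout (DRG KO) tumour. Counts per library totalled between 27.521 M and 41.049 M. At these depths 3 counts, the limit that a count of 0 allows, amounted to 0.0731 to 0.109 CPM in a library. The 10 most abundant genes took 4.85% to 8.06% of counts, and mitochondrial genes 0.798% to 1.63%. Group values are means ± SD of 3 libraries. The p-values measure the spread between these samples, while floors and counting intervals cover counting error only. Whether the libraries of a group came from independent tumours or animals was not tested.

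Grin2d, which encodes the GluN2D subunit of NMDA-type glutamate receptors, was more abundant in the libraries labelled tumour KO than in those labelled tumour WT. Its level was 5.32 ± 0.794 CPM in tumour KO (158, 225 and 186 counts) and 1.83 ± 0.362 CPM in tumour WT (64, 74 and 64 counts), a 2.88-fold difference that held for all 3 KO libraries against all 3 WT libraries. Among the ganglion labels it was 8.85 ± 0.959 CPM in DRG WT and 1.502 ± 0.308 CPM in DRG KO. The targeted gene thus went against the labels in tumour, and each direction below belongs to libraries as labelled. The log2 fold changes were 1.53 (SE 0.19, edgeR adjusted p = 0.00353) in tumour and -2.68 (SE 0.18, edgeR adjusted p = 4.54e-07) in DRG. The exact two-sided permutation p for tumour was 0.1, the smallest that 3 against 3 libraries can give. With replicate 3 as the only WT library the log2 fold change was 1.74 and the adjusted p 0.141, with the spread taken from the KO libraries alone, in a range of 6.93e-06 to 0.141 over the alternatives. Grin2d (ENSMUSG00000002771) is listed on chromosome 7 from 45481307 to 45527802 on the minus strand, and the table counts whole genes, so a deletion of part of the gene would not show in it. Kdelr1, a receptor that returns proteins to the endoplasmic reticulum, overlaps it on the plus strand and measured 165.9 ± 1.06 CPM in tumour WT and 147 ± 21 CPM in tumour KO.

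Whether the 4 groups hold the tissues their labels name was examined next, and the libraries labelled DRG KO had the transcripts of those labelled tumour WT. The library names in the labels begin with MKPC for DRG KO and with MDRG for DRG WT, and the labels do not say what these names stand for. Krt8, a keratin of simple epithelia, measured 4097 ± 285 CPM in DRG KO, 4026 ± 231 CPM in tumour WT and 0 counts in DRG WT. Pdx1, a transcription factor of pancreatic cells, measured 129.7 ± 11.6 CPM in DRG KO, 121.7 ± 12.5 CPM in tumour WT and 1 count over the DRG WT libraries. Plp1, a myelin protein of Schwann cells, measured 153 ± 12.8 CPM in DRG WT, 0.415 ± 0.084 CPM in DRG KO and 0.553 ± 0.256 CPM in tumour WT. Sox10, a transcription factor of Schwann cells and satellite glia, had 13618 counts in DRG WT. Calca, a peptide of pain-sensing neurons, had 452 (4.89 ± 0.887 CPM), and both had 0 counts in the other 9 libraries. Scn10a, the sodium channel of these neurons, measured 0.163 ± 0.0362 CPM in DRG WT, and Col1a1, a collagen of fibroblasts, 9171 ± 311 CPM. The DRG WT libraries thus had few transcripts of pain-sensing neurons. Xist, a chromosome X transcript of female cells, measured 106.8 ± 8.44 CPM in DRG WT and 0.0101 to 0.135 CPM in the other groups. Ddx3y, a chromosome Y gene, measured 107.3 ± 1.18 CPM in DRG WT and 79.19 to 95.88 CPM in the other groups. Both were present in each DRG WT library, Xist at 97.2 to 113 CPM and Ddx3y at 106 to 108.2 CPM. The Y genes Eif2s3y, Uty and Kdm5d measured 44.54, 19.23 and 10.07 CPM in DRG WT. This argues against a single animal behind each DRG WT library, while the number of animals was not tested. Pearson r across 13760 genes was 0.991 to 0.998 between DRG KO and tumour WT libraries, 0.992 to 0.998 among tumour WT libraries, and 0.569 to 0.588 between DRG KO and DRG WT libraries. The edgeR test of DRG KO with tumour WT, added after this was seen, called 0 of 12604 genes, with 94 at an unadjusted p under 0.05. DESeq2 called 0 genes (88 unadjusted) and limma 0 (139 unadjusted). Of the 23 lists tested there, nuclear oxidative phosphorylation, mitochondrially encoded and cytosolic ribosomal protein genes passed with lower medians (-0.18, -0.15 and -0.20) and hypoxia and glycolysis with a higher one (0.11), while with an estimated correlation 0 lists passed (adjusted p = 0.786 each).

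The libraries also parted by gene length. The rank correlation of log2(CPM + 1) with gene length was positive in every library (0.0295 to 0.153). Relative to the tumour WT mean profile, counts fell with gene length in tumour WT replicates 1 and 2 and DRG KO replicate 2. Their log2 slopes were -0.0525, -0.0459 and -0.0306 per doubling of length, and those of the other 9 libraries 0.0838 to 0.168. Slopes of the tumour WT libraries cancel in this reference, so they could not all have the same sign. With the direction of this relative trend as a block, edgeR called 3 genes between DRG KO and tumour WT. All were higher in DRG KO: Rn18s-rs5 (log2 fold change 1.18), Gm10123 (0.62) and Mcc (0.40). With limma's array weights, 5707 genes were called. The columns were separate counts and not copies of one another, since the closest pair of a tumour WT and a DRG KO library had a chi-square of 5.33 per gene, against 3.47 for the closest pair of tumour WT libraries.

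**Figure D1:**
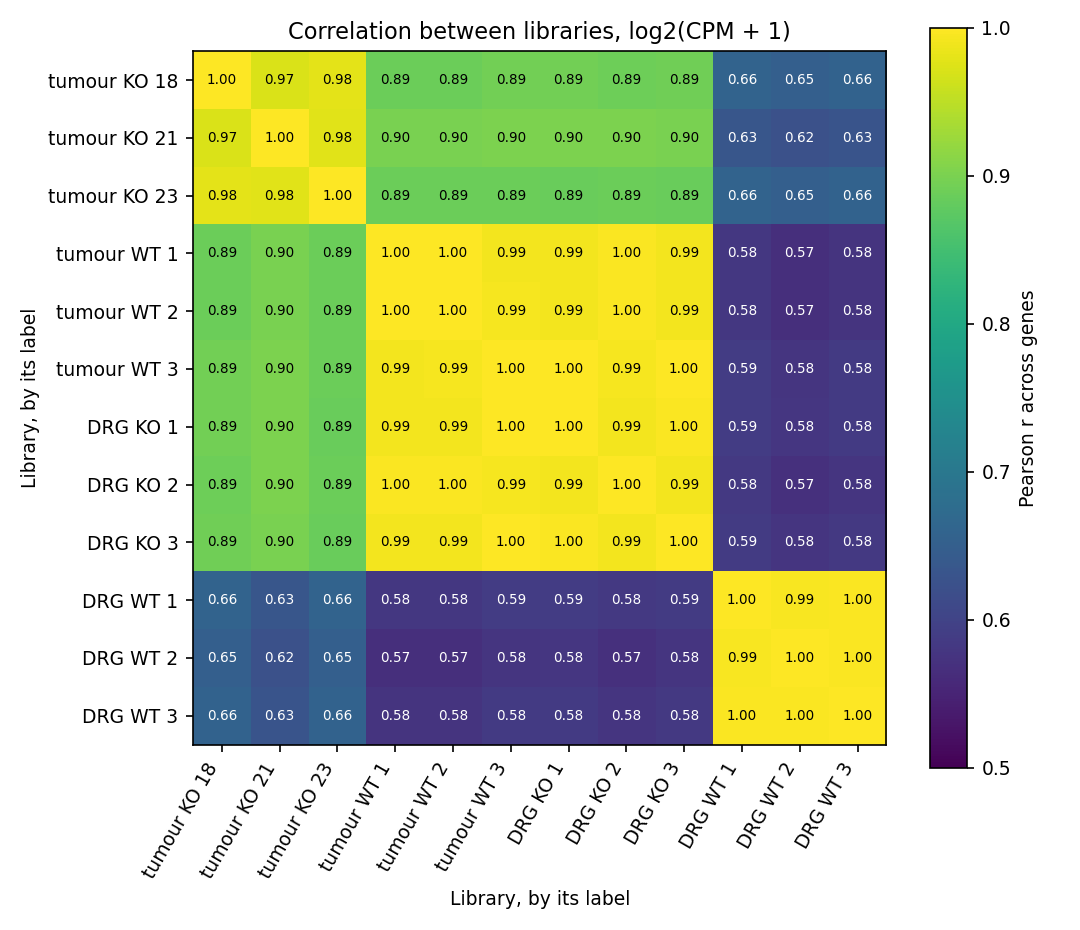
Pearson r across genes on log2(CPM + 1) for each pair of the 12 libraries, named by label. Libraries labelled DRG KO lie with those labelled tumour WT (r of 0.991 to 0.998) and apart from DRG WT (0.569 to 0.588).

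**Figure D2:**
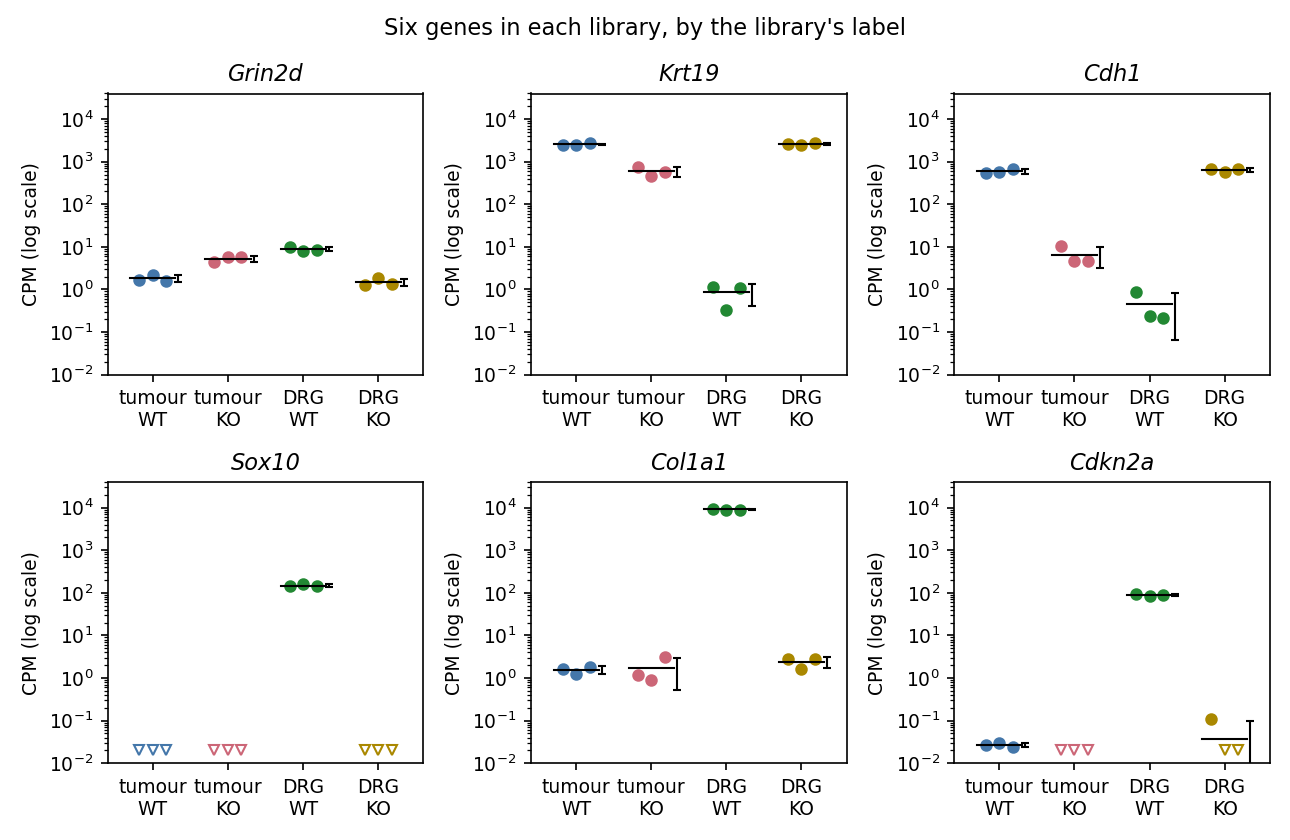
Level of 6 genes in each library on a log scale of CPM, with a line at the group mean and a bar of 1 SD (n = 3), open triangles marking libraries at 0 counts. Krt19 and Cdh1, of epithelial cells, are abundant in tumour WT and DRG KO, while Sox10, Col1a1 and Cdkn2a are abundant in DRG WT alone.

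The comparison of tumour KO with tumour WT was meant to ask what loss of Grin2d goes with in the cancer cells. Genes of the epithelial and the classical pancreatic cancer program were lower in the libraries labelled tumour KO. Most tested members of the mesenchymal, matrix fibroblast and inflammatory fibroblast lists were higher, though these list calls were lost (adjusted p = 0.15, 0.15 and 0.128 with an estimated correlation). Krt7, a keratin of ducts, measured 1073 ± 75 CPM in tumour WT and 0.129 ± 0.179 CPM in tumour KO, and Hnf4a, a transcription factor of gut and liver epithelia, 247.4 ± 24.2 and 0.0915 ± 0.0918 CPM. Ntn1, the axon guidance protein netrin-1, measured 0.570 ± 0.111 CPM in tumour WT and 191 ± 105 CPM in tumour KO. Of 12886 genes tested with edgeR, 4244 (32.9%) passed, 2205 higher and 2039 lower, and 2280 of them differed more than 2-fold. The balance of directions depended on scaling and libraries, at 2634 higher and 1667 lower after rescaling to the same total, and 291 and 629 with WT replicate 3 as the only WT library.

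Each of the 10 lower genes with the greatest fold change had 0 counts in all 3 KO libraries. Ucp2, a mitochondrial carrier protein, was at least 3846-fold lower (107.5 ± 7.64 CPM in tumour WT), Grb7, an adaptor of growth factor receptors, at least 3775-fold, and Il5ra, the receptor chain for interleukin 5, at least 3281-fold. Gata5, a transcription factor of gut and heart, was at least 2748-fold lower. Ugt2b34 and Akr1c19, enzymes that modify steroids and foreign compounds, were at least 2653-fold and 2598-fold lower. Clic6, of the chloride intracellular channel family, Gimd1, Arhgef16, a regulator of Rho proteins, and Slc43a3, a transporter, were at least 2609-fold, 2079-fold, 1789-fold and 1588-fold lower. Their edgeR adjusted p-values lay between 1.89e-06 (Il5ra) and 1e-05 (Gimd1).

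Among the 10 higher genes with the greatest fold change, Ces1g, a carboxylesterase, had 0 counts in tumour WT and 19.6 ± 20.2 CPM in tumour KO (at least 709-fold, edgeR adjusted p = 0.00626). Acta2, smooth muscle actin, measured 0.0371 ± 0.0203 CPM in tumour WT and 30.4 ± 18.3 CPM in tumour KO (log2 fold change 9.56, SE 0.56). Inhbb, a subunit of activin, Cck, the hormone cholecystokinin, and C1s1, a protease of the complement system, had log2 fold changes of 9.06, 9.05 and 8.12. Ccl7, a chemokine that attracts monocytes, measured 0.316 ± 0.0684 CPM in tumour WT and 97.3 ± 26.8 CPM in tumour KO (log2 fold change 8.24, SE 0.26). Dpt, a matrix protein, had 2 counts in tumour WT and 404 in tumour KO, a ratio of 211.9 with a 95% counting interval of 58.3 to 1756. Lrrc75b and Gpnmb, a membrane glycoprotein, had log2 fold changes of 7.37 and 7.30, and Ntn1 of 8.38 (SE 0.48). Ces1g, Inhbb, Cck, C1s1 and Dpt did not pass with the gene length trend as a block (adjusted p of 0.111, 0.0682, 0.149, 0.0657 and 0.131), which leaves 1 WT library to set against the KO libraries. The log2 fold changes of Inhbb and Cck were then 8.46 and 8.91, and the fitted ones of the other 3 were no smaller than before. Over all alternatives their adjusted p ranged from 3.2e-11 to 0.111, 7.11e-13 to 0.0735, 1.13e-09 to 0.18, 4.27e-11 to 0.0775 and 1.26e-07 to 0.15.

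All 12 tested members of the epithelial and ductal list were lower in tumour KO, with a median log2 fold change of -3.74 (camera adjusted p = 4.98e-25, and 0.00458 with an estimated correlation). Elf3, an epithelial transcription factor, went from 85.8 ± 2.06 CPM to 2 counts over the KO libraries (ratio 4592, interval 1271 to 37920), and Muc1, a mucin, from 65.7 ± 3.02 to 0.865 ± 0.294 CPM. Esrp2, a splicing regulator of epithelia, was 10.2-fold lower, at 42.2 ± 1.98 and 4.17 ± 0.576 CPM. All 10 tested members of the classical pancreatic cancer list were lower too, with a median of -8.98, the same with the 2 genes at 0 counts set to their bounds (adjusted p = 6.14e-31, and 0.00458 with an estimated correlation). Lgals4, a lectin of gut epithelium, measured 2331 ± 442 CPM in tumour WT and 1.07 ± 0.658 CPM in tumour KO, and Ctse, the protease cathepsin E, 134.2 ± 15.8 CPM and 2 counts (ratio 7224, interval 1999 to 59650). Hnf1a, a transcription factor of epithelia, had 20.8 ± 2.5 CPM in tumour WT and 0 counts in tumour KO, at least 746-fold lower. Krt19 and Krt8 remained abundant in tumour KO, at 590.4 ± 151 and 1992 ± 378 CPM. Adjusted over the list alone, 12 and 10 members of these lists were lower.

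In the mesenchymal transition list, 8 of 10 members were higher and 2 did not pass, with a median of 1.94 (adjusted p = 5.43e-06, and adjusted p = 0.15 with an estimated correlation). Prrx1, Twist2, Zeb2 and Snai1, transcription factors of mesenchymal cells, were 6.54-fold, 9.31-fold, 4.54-fold and 5.43-fold higher. The inflammatory fibroblast list had 5 of 6 tested members higher and 1 that did not pass, with a median of 6.00 (adjusted p = 0.000462, and adjusted p = 0.128 with an estimated correlation). Ccl2, a monocyte chemokine, measured 1.52 ± 0.38 CPM in tumour WT and 101 ± 42.1 CPM in tumour KO, and Cxcl1, a neutrophil chemokine, 1.60 ± 0.507 and 46.9 ± 21.4 CPM. Cxcl12, another chemokine, reached 238.3 ± 278 CPM and C3, a complement protein, 13.9 ± 11.8 CPM, from 1.87 ± 0.688 and 0.214 ± 0.141 CPM. In the matrix fibroblast list 4 of 6 tested members were higher and 2 did not pass, with a median of 2.08 (adjusted p = 0.00289, and adjusted p = 0.15 with an estimated correlation). Beside Acta2, these were Col3a1 and Col5a1, fibrillar collagens, 51.5-fold and 4.65-fold higher, and Sparc, a matrix protein, 3.85-fold higher. Sparc did not pass without WT replicate 1, 2 or 3 (adjusted p of 0.0865, 0.0748 and 0.122) or without KO replicate 18 or 23 (0.0631 and 0.0565), and its log2 fold change of 1.94 fell to 0.93 without KO replicate 18, with adjusted p in a range of 3.94e-05 to 0.343 over the alternatives. Adjusted over the list alone, 8, 5 and 4 members of these lists were higher.

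Markers of fibroblasts and blood cells were far lower in both tumour groups than in DRG WT. Tumour KO, where members of the fibroblast lists were higher, had only traces of the markers below. Col1a1, the main collagen of fibroblasts, measured 1.58 ± 0.302 CPM in tumour WT and 1.73 ± 1.21 CPM in tumour KO, against 9171 ± 311 CPM in DRG WT. Dcn, a matrix protein of fibroblasts, had 0 and 12 counts in tumour WT and KO, Lyz2, the lysozyme of macrophages, 0 and 19, and Ptprc, the CD45 of blood cells, 10 and 3. Too few members passed the filter to test the lists of macrophages, neutrophils, T and NK cells, endothelial cells, and Schwann cells and myelin (3, 1, 1, 3 and 4 members), and 0 did for B and plasma cells and for dendritic cells and MHC class II.

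Of the 14 cholesterol synthesis genes, 11 were lower in tumour KO and 3 did not pass, with a median of -1.22 (adjusted p = 0.00231, and adjusted p = 0.823 with an estimated correlation). Dhcr24, Idi1, Cyp51 and Mvd, enzymes of the pathway, were 4.04-fold, 2.88-fold, 3.27-fold and 2.80-fold lower. Adjusted over the list alone, 12 were lower. Of the 16 p53 targets, 13 were higher, 2 lower and 1 did not pass, both over all genes and adjusted over the list alone, with a median of 1.00 (adjusted p = 0.00372, and adjusted p = 0.499 with an estimated correlation). Cdkn1a, a brake on the cell cycle, measured 81.8 ± 6.04 CPM in tumour WT and 224 ± 8.45 CPM in tumour KO, and Eda2r, a death receptor, and Ccng1, a cyclin, were 6.99-fold and 2.66-fold higher. Mdm2, which targets p53 for degradation, was lower, at 1020 ± 22.6 and 244.6 ± 99.5 CPM. In the satellite glia list 4 of 5 tested members were lower and 1 did not pass, also adjusted over the list alone, with a median of -1.84 (adjusted p = 0.0113, and adjusted p = 0.172 with an estimated correlation). The members that fell were Entpd2, an enzyme that cleaves extracellular nucleotides, Glul, glutamine synthetase, Aldoc, a glycolytic enzyme, and Apoe, a lipid carrier (85.0-fold, 2.70-fold, 15.7-fold and 3.57-fold), none of them exclusive to glia.

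Cytosolic ribosomal protein genes, read here as a sign of RNA quality, were lower in tumour KO for 9 of 26 members (10 adjusted over the list alone) and did not pass for 17. Their median was -0.53 (adjusted p = 0.0243, and adjusted p = 0.823 with an estimated correlation). Rps29 and Rpl32 were 1.99-fold and 1.96-fold lower, and Rps18 and Rpl4 1.96-fold and 1.62-fold lower. The call was lost without tumour WT replicate 1 (adjusted p = 0.0568), WT replicate 2 (0.0583) or KO replicate 18 (0.146), and after correction for gene length (median -0.42, adjusted p = 0.0725), in a range of 3.95e-05 to 0.823 over the alternatives. Rpl4 did not pass without WT replicate 1, 2 or 3 (adjusted p of 0.0838, 0.083 and 0.0583), nor Rps18 without WT replicate 1 or 2 (0.0701 and 0.067), with highest values of 0.295 and 0.54 over the alternatives. The 12 tested mitochondrially encoded genes had a median of 0.16 (adjusted p = 0.506) and the 10 heat shock genes 0.48 (adjusted p = 0.287).

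Among glutamate receptors, 3 passed the filter, too few for a list test, and all 3 differed. Beside Grin2d, Grik5, a kainate receptor subunit, was lower (15.5 ± 3.68 CPM in tumour WT and 0.546 ± 0.465 CPM in tumour KO, edgeR adjusted p = 0.000309). Grid1, a delta-type glutamate receptor, had 0 counts in tumour WT and 6.88 ± 4.76 CPM in tumour KO, at least 258-fold higher. The lists of glutamate release and handling (median -0.05, adjusted p = 0.478), postsynaptic scaffold and adhesion (0.11, 0.478), presynaptic vesicle release (0.22, 0.297) and immediate early genes (0.20, 0.478) did not pass. Axon guidance and neurotrophic factors had 8 of 18 members higher and 2 lower, a median of 0.53 and an adjusted p of 0.0922. That list passed without KO replicate 18 (adjusted p = 0.0202) or 21 (0.0122), in a range of 0.0122 to 0.707 over the alternatives. Beside Ntn1, Sema3a and Bdnf, a repellent of axons and a neurotrophin, were 13.2-fold and 4.22-fold higher, and Sema3e, another semaphorin, was 6.96-fold lower.

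The remaining tested lists did not pass in tumour. Proliferation genes had a median of 0.12 (adjusted p = 0.455), basal-like pancreatic cancer genes -0.86 (0.107), MHC class I presentation -0.08 (0.633), interferon response -0.42 (0.684) and NF-kB and inflammatory cytokines -0.10 (0.738). Hypoxia and glycolysis had a median of 0.13 with a negative mean (0.948), nuclear oxidative phosphorylation -0.41 (0.107), endoplasmic reticulum stress -0.26 (0.478) and nerve injury and regeneration 0.28 (0.598). Nuclear oxidative phosphorylation passed in 11 of 25 alternatives, among them without WT replicate 3 (adjusted p = 0.00379, range 0.00379 to 0.823). Basal-like genes passed in 10 of 24, among them without KO replicate 21 (0.0149, range 0.0149 to 0.755). The signs of median and camera direction also differed for MHC class I presentation, postsynaptic scaffold and adhesion, and NF-kB genes. Fewer than 5 members passed the filter in tumour and in DRG for pancreatic acinar (3 and 3), pancreatic endocrine (2 and 2), neutrophil (1 and 3), T and NK cell (1 and 3), B and plasma cell (0 and 0), dendritic cell and MHC class II (0 and 3), peptidergic nociceptor (2 and 3), non-peptidergic and itch neuron (1 and 4), myelinated sensory neuron (2 and 3), central nervous system glia (0 and 2), skeletal muscle (3 and 3), adipocyte (3 and 4), erythroid (0 and 0) and cartilage and bone (1 and 1).

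Values of the 3 KO and 3 WT libraries did not overlap for 49% of tested genes, against 10% by chance, and 9 of 25 lists passed (4 up, 5 down), of which the epithelial and classical lists passed with an estimated correlation. The count of genes was 2578 without WT replicate 1 and 2569 without WT replicate 2. It was 1649 with the gene length trend as a block and 920 with replicate 3 as the only WT library, and both of these set 1 WT library against the KO libraries, so that the spread came from the KO libraries alone or from them and the other 2 WT libraries.

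**Figure D3:**
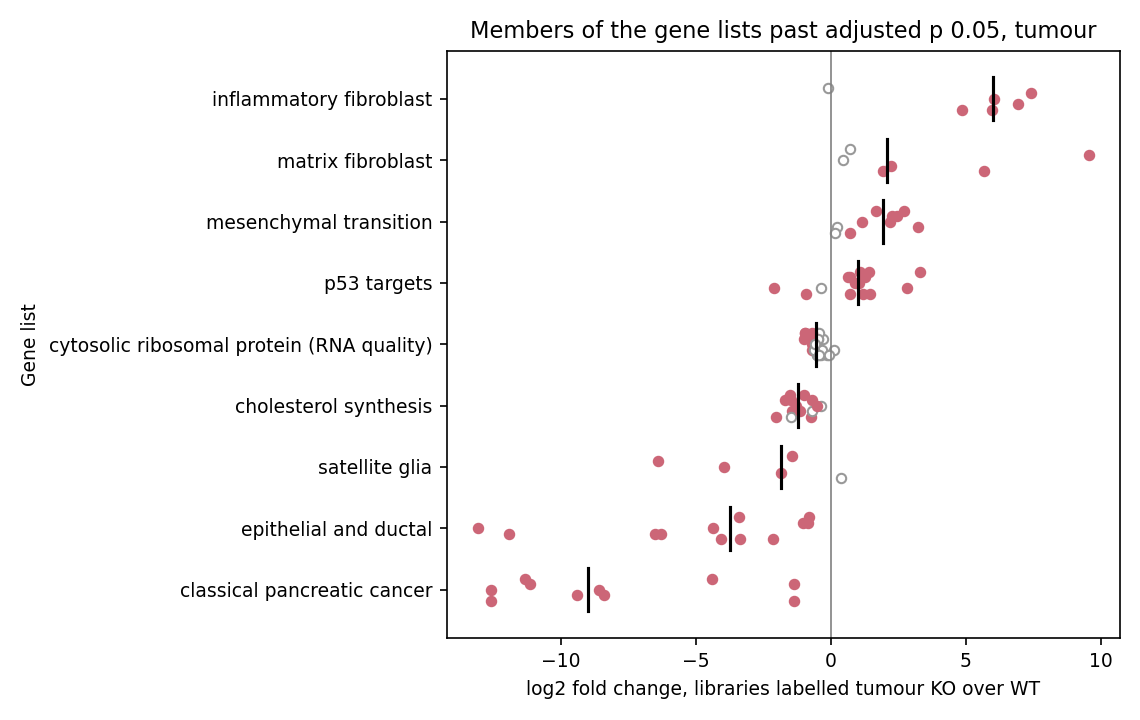
Fitted log2 fold change of each tested member of the 9 gene lists past the threshold in tumour (x axis; tumour KO over tumour WT), with filled points for genes past the threshold and a line at each list's median. All 12 epithelial and 10 classical members lie below 0 (fitted values of genes with few counts depend on the prior count).

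The comparison of DRG KO with DRG WT was meant to ask how ganglia respond to the genotype of the tumour, and it set libraries with the profile of tumour WT against those labelled DRG WT, which had markers of glia, fibroblasts and macrophages and few of neurons. Keratins, proliferation genes and the classical pancreatic cancer program were higher in the libraries labelled DRG KO, and matrix fibroblast genes were lower. Most macrophage and Schwann cell genes were lower too, though these list calls were lost (adjusted p = 0.141 and 0.121 with an estimated correlation). Krt18, a keratin of simple epithelia, measured 2150 ± 163.5 CPM in DRG KO and 0 counts in DRG WT. Col1a1 measured 2.38 ± 0.659 CPM in DRG KO and 9171 ± 311 CPM in DRG WT. Of 13981 genes tested, 10979 (78.5%) passed, 5194 higher and 5785 lower. The larger share turned with other scalings, at 5779 higher and 5250 lower with library totals alone, and 6032 and 5065 after quantile normalization, where 143 calls changed sign.

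Against 0 counts in DRG WT, Krt8 was at least 125900-fold higher in DRG KO, Krt18 at least 66070-fold, Anxa13, an annexin of gut epithelium, at least 12870-fold and Hnf4a at least 7868-fold. Fermt1, an integrin adaptor of epithelia, Gcnt3, an enzyme of mucin glycosylation, Car8, Naip1, a sensor of bacterial proteins, and Cdhr2, a cadherin of the gut brush border, were at least 7042-fold, 5391-fold, 4214-fold, 3435-fold and 2828-fold higher. Lad1, an epithelial anchoring protein, had 1 count in DRG WT (ratio 35100, interval 6300 to 1387000). In the other direction, with 0 counts in DRG KO, Dcn was at least 65440-fold lower, Lyz2 at least 38340-fold, Postn, a matrix protein, at least 30320-fold, and Dio2, a thyroid hormone activating enzyme, at least 20730-fold. Slit3, an axon guidance protein, Fmod, a matrix proteoglycan, Gdf10, a growth factor, and Gpc3, a cell surface proteoglycan, were at least 17330-fold, 15240-fold, 14410-fold and 13100-fold lower. Col1a2, a collagen chain, had 2 counts in DRG KO and 13234 ± 171.5 CPM in DRG WT (ratio 572500, interval 158500 to 4727000), and Lox, which cross-links collagen, 1 count and 1928 ± 94.7 CPM (ratio 166800, interval 29940 to 6589000).

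All 27 proliferation genes were higher in DRG KO, with a median log2 fold change of 5.21 (adjusted p = 1.1e-27, and 0.0308 with an estimated correlation). Kif11, a mitotic motor, measured 2.11 ± 0.0755 CPM in DRG WT and 131.7 ± 4.18 CPM in DRG KO, and Aurkb, a mitotic kinase, 1.57 ± 0.105 and 86.8 ± 3.08 CPM. The 11 epithelial and 10 classical pancreatic cancer genes tested were all higher, with medians of 10.37 and 11.47, or 9.90 and 9.41 with genes at 0 counts set to their bounds (adjusted p = 6.23e-17 and 5.16e-10, and 0.0366 and 0.0308 with an estimated correlation). Krt19 measured 0.859 ± 0.456 CPM in DRG WT and 2603 ± 138 CPM in DRG KO, and Foxa2, a transcription factor of endoderm, 0 counts and 81.3 ± 3.52 CPM. All 5 basal-like pancreatic cancer genes tested were higher, among them Areg, a growth factor, and Lamc2, a laminin chain, with a median of 7.71, or 7.01 at the bound (adjusted p = 1.13e-06, and 0.0366 with an estimated correlation). All 14 cholesterol synthesis genes were higher, with a median of 1.99 (adjusted p = 0.000956, and adjusted p = 0.524 with an estimated correlation), among them Lss and Hmgcr, enzymes of the pathway (4.86-fold and 4.04-fold). The counts adjusted over the list alone were the same, at 27, 11, 10, 5 and 14.

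All 15 matrix fibroblast genes were lower in DRG KO, with a median of -10.87, or -10.63 at the bound (adjusted p = 1.45e-23, and 0.0308 with an estimated correlation). Sparc measured 9995 ± 486 CPM in DRG WT and 40.7 ± 1.86 CPM in DRG KO. Of 11 inflammatory fibroblast genes, 9 were lower, 1 higher and 1 did not pass, with a median of -5.78 (adjusted p = 9.54e-05, and adjusted p = 0.0544 with an estimated correlation), and Col14a1, a collagen, went from 1161 ± 27.2 CPM to 5 counts. Of 13 macrophage genes, 12 were lower and 1 higher, with a median of -11.81, or -10.39 at the bound (adjusted p = 3.84e-11, and adjusted p = 0.141 with an estimated correlation). Cd68, a lysosomal protein of macrophages, measured 74.7 ± 4.39 CPM in DRG WT and 2.61 ± 0.324 CPM in DRG KO. Of 10 Schwann cell and myelin genes, 8 were lower and 2 higher, with a median of -7.32 (adjusted p = 8.51e-07, and adjusted p = 0.121 with an estimated correlation), and Pmp22, a myelin protein, was 23.5-fold lower. Of 7 satellite glia genes, 5 were lower, 1 higher and 1 did not pass, with a median of -3.39 (adjusted p = 0.00362, and adjusted p = 0.112 with an estimated correlation). Adjusted over the list alone, 15, 9, 12, 8 and 5 members of these lists were lower.

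All 5 glutamate receptors tested were lower in DRG KO, with a median of -11.85, or -9.87 at the bound (adjusted p = 9.54e-05, and adjusted p = 0.0544 with an estimated correlation). Gria3, an AMPA receptor subunit, measured 93.0 ± 5.96 CPM in DRG WT and had 2 counts in DRG KO (ratio 4027, interval 1114 to 33250). Gria4, another AMPA subunit, and Grik3, a kainate subunit, had 54.5 ± 2.31 and 32.3 ± 1.39 CPM in DRG WT and 0 counts in DRG KO, at least 1571-fold and 932.6-fold lower. Of 11 nerve injury and regeneration genes 7 were lower, 3 higher and 1 did not pass, with a median of -1.01 (adjusted p = 0.0292, and adjusted p = 0.163 with an estimated correlation). Gap43, a growth cone protein, was 79.8-fold lower and Sprr1a, induced by axon injury, 26.0-fold higher. This call was lost in 13 of 25 alternatives, among them without DRG WT replicate 2 (adjusted p = 0.122), in a range of 1.25e-06 to 0.246. Of 10 mesenchymal transition genes 9 were lower and 1 higher, with a median of -1.42 (adjusted p = 0.026, and adjusted p = 0.443 with an estimated correlation). Of 14 interferon response genes 12 were lower and 2 did not pass, with a median of -3.70 (adjusted p = 0.00077, and adjusted p = 0.485 with an estimated correlation), among them Ifit3 and Stat1 (49.2-fold and 11.9-fold). Of 10 MHC class I presentation genes 8 were lower and 2 higher, with a median of -1.88 (adjusted p = 0.0374, and adjusted p = 0.512 with an estimated correlation), and B2m, the light chain of MHC class I, was 5.01-fold lower. Adjusted over the list alone, 5, 7, 9, 13 and 8 members of these lists were lower.

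Markers of sensory neurons were scarce even in DRG WT, where Calca measured 4.89 ± 0.887 CPM, Prph, a neurofilament protein, 4.16 ± 0.393 CPM, and Scn10a, the sodium channel of pain-sensing neurons, 0.163 ± 0.0362 CPM. The DRG groups differ in cell content, so the genes listed for RNA quality cannot be read here as quality alone. Of these, 10 of 12 mitochondrially encoded genes were lower in DRG KO and 16 of 26 cytosolic ribosomal protein genes higher. Their medians of -0.84 and 0.40 did not pass (adjusted p = 0.237 and 0.151), but did in 10 and 11 of 25 alternatives, among them every limma fit (ranges 0.00134 to 0.718 and 0.00603 to 0.741). Endothelial genes (median -3.02, adjusted p = 0.237) and the remaining 11 of the 29 lists tested did not pass. Of those 29 lists, 15 passed (5 up, 10 down), and 5 with an estimated correlation: proliferation, epithelial and ductal, classical and basal-like pancreatic cancer, and matrix fibroblast. Without DRG KO replicate 2, whose gene length trend differed from the other 5, 11482 genes passed. Hypoxia and glycolysis genes passed in 13 of 25 alternatives, among them without DRG KO replicate 2 (adjusted p = 0.0282) or DRG WT replicate 2 (0.0337). Endoplasmic reticulum stress genes passed in 15 of 25, also without each of these libraries (0.0392 and 0.000646). The ranges were 0.00751 to 0.718 and 0.000639 to 0.6. The p53 targets passed in 15 of 25, among them without DRG WT replicate 1 (0.046) or 2 (0.0266), in a range of 6.06e-05 to 0.524. Postsynaptic genes passed in 9 of 25, among them without DRG WT replicate 2 (0.0494), in a range of 6.85e-05 to 0.586. Values did not overlap between the DRG groups for 81.3% of tested genes, against 10% by chance.

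The last comparison asked whether the KO effect differed between tumour and ganglia. Genes abundant in the libraries labelled tumour WT led it, being lower in tumour KO than in tumour WT and higher in DRG KO than in DRG WT. Hhex, a transcription factor of liver and pancreas, measured 60.5 ± 4.09 and 4.79 ± 0.375 CPM in tumour WT and KO, and 1.44 ± 0.0601 and 65.1 ± 2.00 CPM in DRG WT and KO, a difference of log2 fold changes of -9.12. The differences were -16.91 for Dnajc22, -17.46 for Misp, an actin-binding protein of mitosis, and -11.64 for Paqr5, a progesterone receptor of the membrane. Ctse, at 2 counts in tumour KO and 1 count in DRG WT, had a fitted difference of -25.79, which depends on the prior count. Grin2d differed by 4.14 (SE 0.26, edgeR adjusted p = 1.16e-07). Of 13744 genes tested, 9359 passed, 4334 with a positive and 5025 with a negative difference, and the median over all tested genes was -0.10. The larger share turned after rescaling to the same total (5139 positive and 4400 negative) and without some of the libraries, such as tumour KO replicate 18 (4752 and 4633).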

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

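The tests of mixing, of library identity, of a ganglion response, of overlapping genes, of gene length and of exchanged labels were chosen only after the data had been seen. The effect of the KO label differed between libraries labelled tumour and DRG for 9359 genes, by a test of the difference itself. The differences of log2 fold changes were -16.91 for Dnajc22, -17.46 for Misp, -25.79 for Ctse, -9.122 for Hhex and -11.64 for Paqr5, and 4.137 for Grin2d. Of 100 ways to split the libraries within labelled tissues, the real one alone reached that count (1 of 100). The highest other gave 7364 genes. Libraries labelled DRG KO and DRG WT differ in content, so splits that mix them widen the spread. The real split was thus favoured in advance, and no conclusion about chance is drawn from its rank.

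These differences go with the content of the libraries labelled DRG KO, which matched tumour WT at a Pearson r of 0.9909 or higher. Ganglia with tumour cells mixed in were argued against, since the 127 genes above 100 CPM in DRG WT and under 0.5 CPM in tumour WT had a median of 0.00953% of their DRG WT level in DRG KO. A response of ganglia to the tumour genotype was argued against as well, since 13 genes on chromosome 4 that are near absent from the tumour libraries were at 0.0306% of their DRG WT level. Both tests take DRG WT, where markers of sensory neurons were scarce, as the reference for ganglia. The values are consistent with cancer cells like those labelled tumour WT under the DRG KO label, whose library names begin with MKPC, and how this came about stays open. Whether ganglia respond to the genotype of the tumour, the biological question of the design, stays untested.

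Grin2d was higher under the tumour KO label and lower under the DRG KO label. Reads of overlapping genes at a constant share were argued against. Kdelr1, the only 1 of 3 at least as abundant as Grin2d, moved by -0.185 (log2, SE 0.115). Gm45441 measured 0.224 and 0.237 CPM and U4 0 and 0.068 CPM in tumour WT and KO. Kdelr1 was far more abundant than Grin2d, at 165.9 and 147 CPM. A change in a small share of its reads would not show in its total and stays open. The gene length trend was argued against by a log2 fold change of 1.447 after its correction. An exchange of the KO and WT labels in tumour cannot be told apart from correct labels, since an edited gene can still be transcribed. The lowest count in a library labelled tumour WT was 64, and no outcome of this test could have argued against an exchange. A knockout that leaves transcripts of Grin2d in place is a biological explanation that stays open, and was not tested.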

How the results depend on the processing

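The tests with RLE factors, library totals, DESeq2, filterByExpr, gene length and WT replicate 3 alone were chosen only after the data had been seen. Limma was the main test fixed in the design, and edgeR replaced it once the values were taken as counts. No call of the named genes and lists followed through the alternatives turned direction, while the medians of 7 tumour and 3 DRG lists that did not pass changed sign in some alternatives. Among all genes, 143 DRG calls changed sign after quantile normalization and up to 65 calls of the difference did so in limma fits. For tumour genes (4244 past the threshold) leaving out 1 library gave 2569 to 4865, WT replicate 3 as the only WT library 920, and the gene length trend as a block 1649. Both of the last set 1 WT library against the KO libraries, and the cause was not tested further. Of the named tumour genes followed, 21 lost their call in at least 1 alternative, and of the tumour lists 7 lost and 3 gained one. The lists past the threshold in tumour were 2 with an estimated correlation, and 8 to 11 with 1 library left out. In DRG they were 5 with an estimated correlation, 28 with fry, and 15 to 18 with 1 library left out, and the cause was not tested. DRG genes ranged from 10211 to 11482 and the difference from 8850 to 9740 with 1 library left out. The DRG and difference genes followed kept their calls throughout. With the replicate block 10416 DRG genes and 20 DRG lists passed, against 10979 and 15. Libraries with the same number did not deviate together (r of -0.226, -0.243 and -0.0512), so the numbers were not taken as pairs. No paired analysis was possible in tumour because the groups share no replicate numbers. The median log2 fold change of all tumour genes was 0.118 after rescaling to the same total (0.0128 as reported), that of all DRG genes 0.11 after quantile normalization (-0.0497) and 0.0786 with library totals alone, and that of the difference 0.0942 after rescaling (-0.101). Depth sets a floor of 0.0731 to 0.109 CPM per library, below which absence and a low level look the same.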

Other observations

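The tests of host cells, of clonal differences, of the shared loss on chromosome 4, of gene length, of copy number and of the Mdm2 region were chosen only after the data had been seen. Among protein-coding genes with at least 10 CPM in DRG WT, the only ones assessed, 13 consecutive ones on chromosome 4, between 87688162 and 95815176, had means under 0.3 CPM in the libraries labelled tumour WT and tumour KO. No gene was assessed between Cdkn2b, which ends at 89229276, and Caap1, which starts at 94388318. The run holds Cdkn2a and Cdkn2b, inhibitors of the cell cycle, Mtap, an enzyme of methionine salvage, and Jun, a transcription factor. Cdkn2a measured 89.04 CPM in DRG WT and had 3 counts in tumour WT and 0 in tumour KO, and Jun 139.2 CPM with 3 and 0 counts. Summed over the run, there were 39 counts in tumour WT, 20 in DRG KO and 0 in tumour KO. The same search returned 4 Hoxc genes on chromosome 15 in all 9 libraries and 5 Hoxa genes on chromosome 6 in tumour KO, runs of developmental genes that need no loss of DNA. The 13 genes shared by both tumour groups are consistent with a loss they have in common, but DNA was not examined and silent genes stay open.

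The lower epithelial and classical genes in tumour KO were weighed against technical explanations. Host cells in the KO samples were argued against, since the 13 genes, which the search also returned from tumour WT alone, had 0 counts in tumour KO and gave an upper limit of 0.00363% where the median fall would need 92.5%. The length trend was argued against by a median of -3.72 for the epithelial list after its correction. After each chromosome's median was subtracted, the epithelial median was -3.863. The largest chromosome median was 0.477 (chromosome 8), far smaller than the fall of the list. The subtraction could therefore not have brought the list near 0, and no conclusion about copy number is drawn from it. Clonal differences between the cell lines that do not come from Grin2d cannot be told apart from an effect of Grin2d, as 4 autosomes had medians shifted by over 0.2 one way in all 3 KO libraries. An effect of Grin2d, the biological explanation of the design, stays open.

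Chromosomes 6, 8, 14 and 19 had medians shifted by over 0.2 (log2) one way in tumour KO replicates 18, 21 and 23 (medians of -0.458, -0.448 and -0.441 on chromosome 6, and 0.44, 0.489 and 0.426 on chromosome 8). Chromosome 4 went one way with a smaller value in replicate 18 (0.156, 0.459 and 0.391). It passed with camera (adjusted p = 0.00433, and adjusted p = 0.958 with an estimated correlation). Chromosome 9 was higher in replicate 18 and lower in replicates 21 and 23 (0.227, -0.198 and -0.232), so the KO libraries also differed among themselves. Pearson r among them was 0.971 to 0.979, against 0.992 to 0.998 among tumour WT libraries. Relative to the tumour WT mean, no autosome median exceeded 0.0858 in size in the tumour WT and DRG KO libraries. Whether the tumour WT libraries were repeats of the same cell line was not tested. If they were, the p-values rest on fewer independent WT units than libraries. With each of chromosomes 6, 8, 14 and 19 divided at its middle gene, 7 of the 8 parts were shifted by over 0.2 in all 3 libraries and the other, on chromosome 14, by -0.252, -0.232 and -0.185, and copy number cannot be told apart from other causes. Mdm2 was higher in tumour WT, while the other 7 tested genes within 0.5 Mb had a median of 0.0941 (log2 WT over KO, range -0.19 to 11.2), which argues against a gain of that whole span. The 11.2 belongs to the immediate neighbour of Mdm2, ENSMUSG00000120638 (117.1 CPM in tumour WT and 0.0492 in tumour KO). That value far exceeds the 2.085 of Mdm2, while Slc35e3, the next tested gene, had -0.05157. A narrower gain was not tested and stays open.

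Splits of the 6 libraries were too few (10) for a share under 0.05. In tumour 1 of 10 reached the count, the real one with 4244 genes, and the highest other gave 0. In DRG it was also 1 of 10, with 10979 genes and a highest other of 0. Between DRG KO and tumour WT the real split gave 0 genes, a count that every split reaches (10 of 10), so this says nothing about chance. The highest other gave 7353, with tumour WT replicates 1 and 2 and DRG KO replicate 2 on one side. These are the libraries whose counts fell with gene length relative to the tumour WT mean profile.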
